A study of Mus musculus with 6 samples.

How the data were processed

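The samples were libraries of guide sequences amplified from genomic DNA of FLAMs, macrophages grown from mouse fetal liver cells of a Cas9-expressing C57BL/6J strain with the cytokines GM-CSF and TGF-beta, which hold them in a state like that of alveolar macrophages. Cells carrying a pool of knockout guides were grown for 2 weeks, per the labels. They were then sorted by surface Siglec-F into high and low fractions, or taken unsorted as input. Each of the 3 groups held 2 libraries, 6 in all. The labels give the molecule as RNA while the extraction text describes genomic DNA, and the values were read as guide counts from DNA. The guide library, the number of cells per sort, the sort gates and whether replicates were separate cultures are not given in the sources used here.

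The submitters' notes name FastQC 0.11.5, cutadapt 2.9 and MAGeCK, a program for pooled knockout screens, with no version. The deposited table of normalized guide signal held reads of each guide multiplied by 1 factor per library, as the authors scaled them. Dividing each library by its smallest non-zero value gave whole reads, within 0.01 reads, in 100% of values, so read numbers were recovered from it. A second deposited table gave, per guide, the authors' log2 fold change of high over low, computed from group means plus 1, and other columns in which the deposited counts of a pair of libraries share a cell. Its values were per guide although it is named as a gene summary, so its order of genes was made here from the median guide.

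The table held 79612 guides, 1000 of them non-targeting, and 19672 gene names. A spreadsheet had turned 24 names into dates, and 2 of these merged different genes and were left out, with their 16 guides. Guide identifiers are positions in the GRCm38 mouse genome: 75785 of 75832 identifiers (99.938%) fell inside the gene they name in GENCODE release 21 for mouse, against 23 after the names were shuffled.

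Guides with a mean of at least 10 normalized counts over the 6 libraries were kept, 60188 guides (75.6%), and the 16492 genes with at least 3 of them were tested. Of these, 10712 had 4 guides and 5780 had 3. Guides were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend) on log2 of the normalized count plus 5. The 3 groups shared 1 estimate of spread with 3 residual degrees of freedom. Genes were scored by alpha-RRA, which asks whether a gene's guides lie nearer the top of the list than chance, with alpha 0.25 and 2000000 simulated rank sets. Benjamini-Hochberg adjustment was made over genes in each direction, and genes under 0.05 were called. Fold changes are means over a gene's guides with the SD between guides, relative to the median guide of the same comparison. They are on the scale of log2(value + 5) and understate changes of guides with few reads. Tables were handled with the R package data.table, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

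Gene lists were tested with camera at a preset correlation of 0.01 on medians over guides. Camera with an estimated correlation was run beside it. So was fry, which asks whether a list moves on balance, without comparing it with other genes. Fry was run on values not centred on the median guide, so its direction includes any shift of all guides. Of 30 lists, 29 had the 5 tested members required. The comparisons, the lists, the alternatives not described as added later and the rule for genes named were fixed before the data were examined. The rule takes Siglecf first. It then takes up to 15 genes higher and 10 lower in Siglec-F low past 0.05, with at least 3 guides moving that way in both differences of same-numbered libraries. Against input it takes up to 5 per direction. Where fewer than 5 qualified, the 5 of smallest score are given as values. It adds up to 4 members of each list past its test, and up to 3 members of the GM-CSF signalling, TGF-beta signalling and alveolar macrophage transcription factor lists. It also adds the 10 best genes per direction in the authors' table. Genes named outside the rule are said to be chosen after their values were seen. Results of a few genes that the rule takes are not reported here.

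The alternatives were pseudocounts of 1 and 20, no filter, a mean of at least 50, scaling on non-targeting guides or to equal totals, gene medians, an alpha of 0.1, thresholds of 0.1 and 0.25, edgeR 4.0.16 on recovered reads, a replicate block, fits on the compared groups alone, and leaving out each library in turn. A fit that leaves a group with 1 library assumes that this library varies like the other groups. On simulated data with the same library sizes, the limma test called 5, 38, 43 and 50 of 50 genes changed 4, 16, 32 and 64-fold, with 3 calls among 16292 unchanged genes. Of 50 unchanged simulated lists, 0 had a camera p under 0.05. Simulated guides were drawn independently, from the same mean profile in every library apart from the changed genes. Genes were thus uncorrelated and the inputs shared a profile, unlike the real ones. The simulation cannot show false list calls from correlated genes, and its recovery may not hold for the real libraries.

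Guide statistics rest on the spread between libraries, which may be technical, since the labels do not say that replicates were separate cultures. Gene p-values by alpha-RRA compare the ranks of a gene's guides with random ranks. Camera compares a list with the other genes. Neither measures how far separate cultures would differ. Intervals on shares of reads are 95% Wilson intervals and cover counting error only, because amplified reads are not independent molecules.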

Results

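The screen measured how often knockout guides occurred in FLAMs with high or low surface Siglec-F, a sialic acid binding lectin carried by alveolar macrophages and eosinophils, and in unsorted input cells. Guides that are more frequent in the low fraction mark genes whose loss goes with less surface Siglec-F. The Siglec-F high libraries held 24105356 and 28077397 guide reads, the low libraries 26215927 and 24743149, and the input libraries 40276374 and 34364774.

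Reads were spread very unequally. A guide against Cnot6l, a subunit of the CCR4-NOT deadenylase, took 35.4% of Input replicate 1 (95% Wilson interval 35.3 to 35.4%), and its 16 most abundant guides made up 90% of the reads, while 66.5% of its guides had 1 to 15 reads. In Input replicate 2 the same guide took 1.12%, and 0.106% of guides had 1 to 15 reads. In Siglec-F high replicate 2 the most abundant guide, at 7.87%, targeted Itgam, the integrin CD11b. Between 29.5% and 49.4% of guides had 1 to 15 reads in the sorted libraries. Spearman's rho across guides, which are not independent replicates, was 0.735 between the high libraries, 0.776 between the low libraries and 0.483 between the inputs. Input replicate 1 had a higher rho with the 4 sorted libraries (0.746 to 0.772) than with Input replicate 2.

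**Figure D1:**
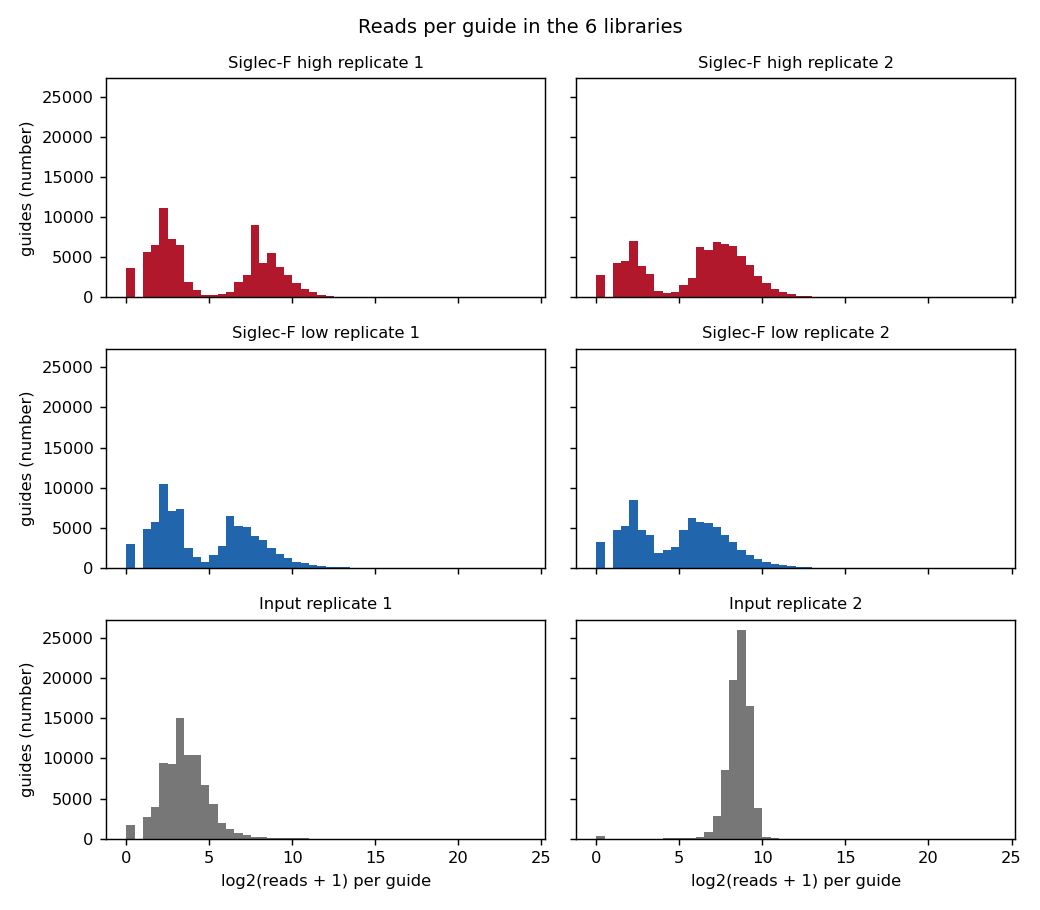
Number of guides (vertical axis) by log2(reads + 1) per guide (horizontal axis) in each of the 6 libraries. The sorted libraries have a group of guides at 1 to 15 reads and a group with more, Input replicate 1 has 66.5% of guides at 1 to 15 reads, and Input replicate 2 has 0.106%.

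Guides against genes that cells need to grow were less frequent than non-targeting guides in the unsorted cells. Relative to the median non-targeting guide, the median guide of 82 cytosolic ribosome genes was at log2 -2.32 in Input replicate 1 and -0.88 in Input replicate 2, and that of 39 proteasome genes was at -1.58 and -0.59. Guides of the growth restraint list, of genes that check growth, were at 0.68 and -0.02. Guides of 1079 olfactory receptor genes, which macrophages do not use, were at -0.32 and -0.10. In Input replicate 1, 36.9% of ribosome guides had under 10% of the median non-targeting reads, against 3.8% of non-targeting guides. In Input replicate 2 the shares were 0.610% and 2%. The median non-targeting guide had 14 reads in Input replicate 1 and 438 in Input replicate 2, so the bound lay near the floor in the first. No test between libraries was made of the values in this paragraph, which are given library by library. The ribosome value of Input replicate 2 was set against random gene sets later.

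**Figure D2:**
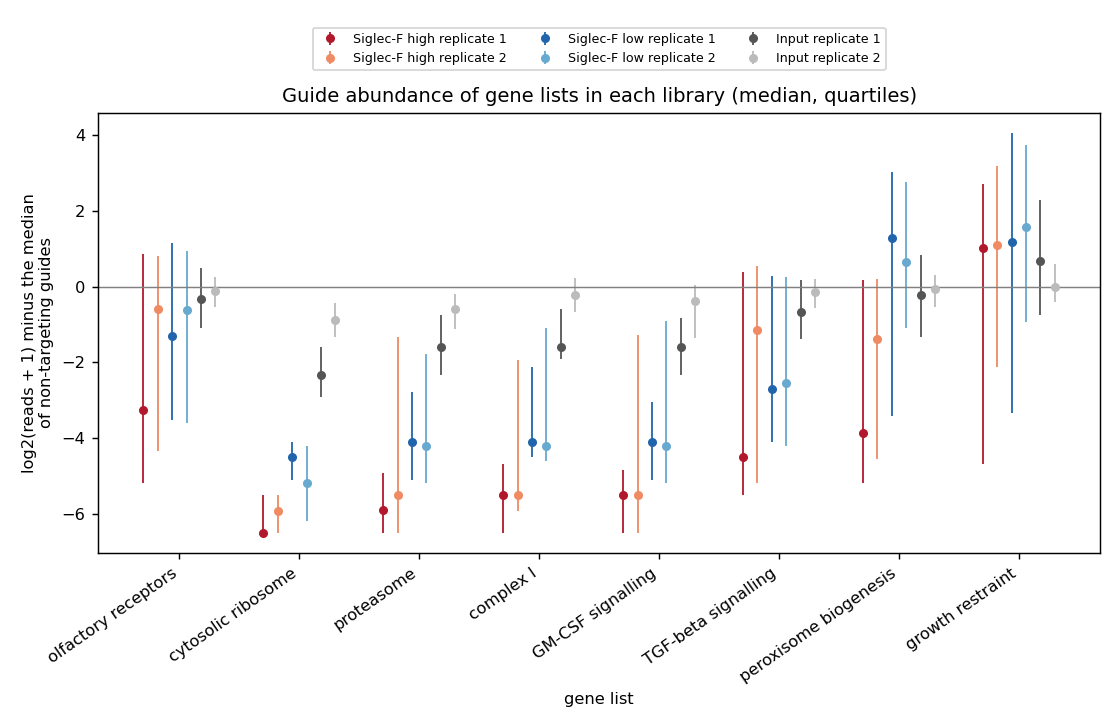
Median log2(reads + 1) of the guides of 8 gene lists minus the median of non-targeting guides (vertical axis, log2), by list (horizontal axis), with bars from the lower to the upper quartile of guides and 1 colour per library. Cytosolic ribosome guides lie at -6.50 to -4.51 in the 4 sorted libraries, at -2.32 in Input replicate 1 and at -0.88 in Input replicate 2. The median non-targeting guide had 180 and 181 reads in the high, 67.5 and 72.5 in the low and 14 and 438 in the input libraries. Guides near the floor lie lower where that median is higher, so the order of libraries does not by itself measure loss.

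The comparison of Siglec-F low with Siglec-F high asks which knockouts change surface Siglec-F. Siglecf itself, the gene of the sorted protein, had the smallest score among genes higher in the low fraction: its guides were 33.9-fold more frequent in the low libraries (log2 5.08 ± 0.70, SD over 4 guides), and all 4 guides were higher in both same-numbered differences. Its limma and alpha-RRA adjusted p was 0.132, over the threshold. Siglecf lies on chromosome 7 at 43351341 to 43359531, + strand, in GRCm38 (ENSMUSG00000039013.16). The guide at 43351871 in exon 3 of transcript Siglecf-201 had 15078 ± 6234 normalized reads in the low libraries and 380 ± 362 in the high libraries (SD, n = 2 each). The guide at 43352204 in exon 4 had 4659 ± 1911 and 534 ± 643. In exon 6, the guide at 43355015 had 1129 ± 355 and 34.1 ± 2.63, and the guide at 43355210 had 6002 ± 2239 and 241 ± 242. By the authors' scaling 1 read counted 1.80 in high replicate 1 and 0.316 in high replicate 2. These SDs depend on that scaling and do not measure how well the replicates matched in reads. In recovered reads, high replicates 1 and 2 had 20 and 102 for the guide at 43355015. For the guide at 43351871 they had 354 and 394. Siglecf passed the threshold in 11 of 19 other settings, with adjusted p from 0.00206 to 0.913, and was above the median guide in 19. The fits without either Input replicate had the same fold (log2 5.08 ± 0.70) and residual spread as that on the sorted libraries alone. A lone input library adds no residual spread, so these passes are not separate. Siglecf did not pass without any 1 of the 4 sorted libraries. Over the 19 settings its log2 ran from 4.43 to 5.50.

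**Figure D3:**
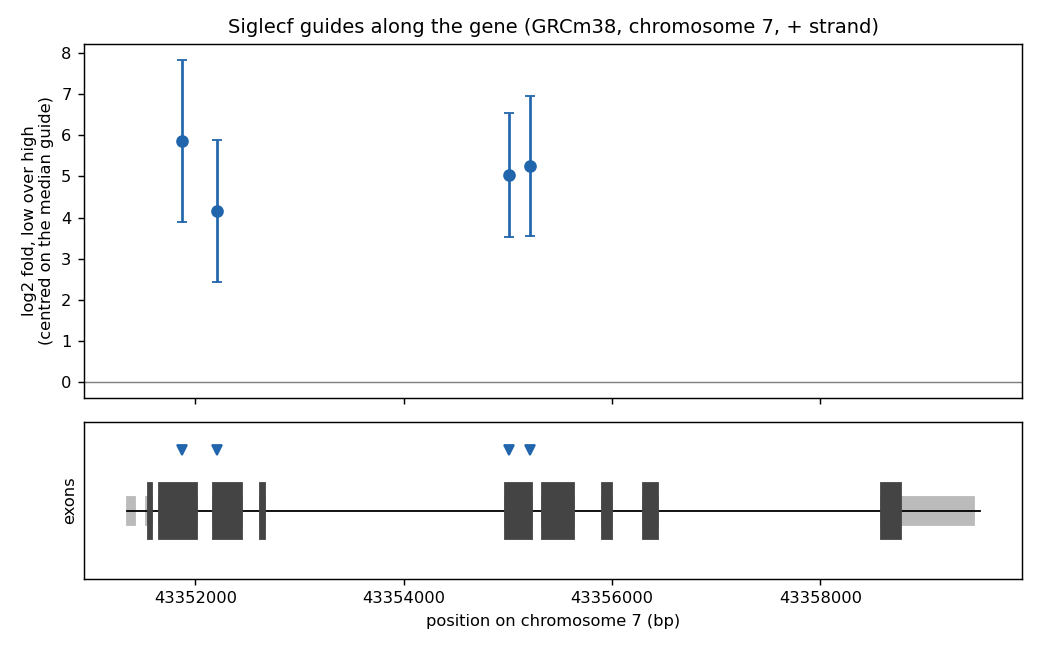
Upper panel: log2 fold of low over high, relative to the median guide (vertical axis), of the 4 Siglecf guides at their position on chromosome 7 (horizontal axis, bp); points are limma estimates and bars their standard errors, over 2 libraries per group. Lower panel: exons of Siglecf-201, with coding parts dark; the guides lie in exons 3, 4 and 6 and have log2 folds of 4.16 to 5.86.

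Behind Siglecf, the genes with the smallest scores in the direction of the low fraction were Ociad1, Apc, Rwdd1 and Pptc7. Guides of Apc, which restrains Wnt signalling, had a log2 fold of 3.29 ± 0.89 over 4 guides, and those of Rwdd1 3.42 ± 2.20. Ociad1 had 3.72 ± 3.03 over 3 guides and Pptc7, a mitochondrial phosphatase, 1.61 ± 4.14 over 4, so their guides disagreed. In the opposite direction, guides of Lcmt1, which methylates the catalytic subunit of a protein phosphatase, had -3.72 ± 1.70. Guides of Lmnb1, of the nuclear lamina, had -3.28 ± 0.33, those of Lgals3, which encodes galectin-3, -2.22 ± 3.97, those of Pdzk1ip1 -2.23 ± 2.29 and those of Vmn1r114, a vomeronasal receptor, -0.995 ± 2.73. None of these genes passed the threshold: adjusted p was 0.19 to 0.195 for the first 4 and 0.115 for Lcmt1, and from 0.416 to 0.712 for the rest.

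Over 16492 genes limma with alpha-RRA called 0 genes higher and 0 lower in the low libraries, with 885 and 848 at an unadjusted p under 0.05. Random ranks alone would put a share of 0.05 of genes there in each direction. Such counts, here and in the comparisons below, therefore do not by themselves mark weak effects. On the same libraries edgeR called 4 higher (Siglecf with adjusted p 0.0206, Pex6 0.0165, Ociad1 0.033 and Apc 0.0474) and 1 lower (Lcmt1, 0.033). limma on the sorted libraries alone called 4 higher, among them Siglecf and Cic, a transcriptional repressor that acts downstream of receptor signalling (both 0.00412), and Apc (0.0412); it called 0 lower, with 842 at an unadjusted p under 0.05. Without either Input replicate, limma had the same residual spread as on the sorted libraries alone, so its calls were not separate from those. Without any 1 of the sorted libraries it called 0 higher and 0 lower, with 838 to 874 in each direction at an unadjusted p under 0.05. Scaling on non-targeting guides gave 4 higher and 1 lower, and scaling to equal totals 7 and 1. The median guide lay at -0.22 as deposited, 0.29 with non-targeting scaling and -0.71 with equal totals.

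Genes of peroxisome biogenesis, whose products import enzymes into peroxisomes or build their membrane, were higher in the low fraction as a list. The 12 tested members had a median log2 of 3.04 and a mean of 2.62, and 11 lay above 0 (camera adjusted p = 6.99e-07). The call was lost with an estimated correlation (adjusted p = 0.928), and fry gave 0.352. With the preset correlation the call held without each library in turn. Adjusted over the list alone, 8 members passed, and 0 passed over all genes. Examples were Pex6 (log2 4.06 ± 0.91 over 4 guides) and Pex16 (3.58 ± 2.22 over 3). Pex11a was at -0.30 ± 2.62.

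**Figure D4:**
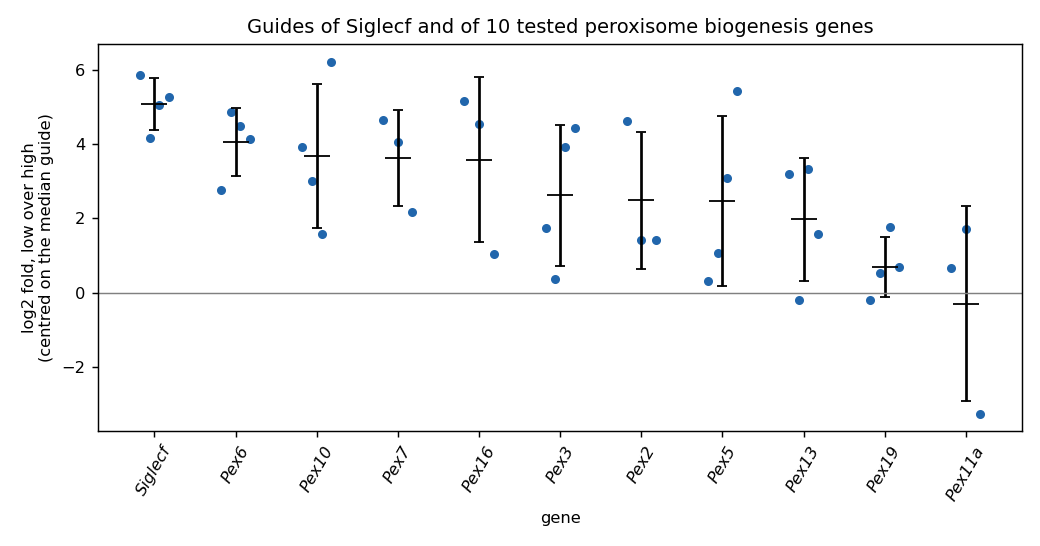
Log2 fold of low over high, relative to the median guide (vertical axis), of each guide (points) of Siglecf and 10 of the 12 tested peroxisome biogenesis genes (horizontal axis), with the mean and SD over guides (black). The gene means drawn run from 4.06 for Pex6 down to -0.30 for Pex11a, and Siglecf is at 5.08.

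Genes of N-glycan assembly, which build and attach the sugar chains of surface proteins, were also higher in the low fraction as a list of the 20 of 41 genes that passed the filter (median log2 0.78, mean 0.93, 16 above 0, camera adjusted p = 0.0371). The adjusted p was 0.928 with an estimated correlation and 0.123 for all 41 genes with no filter. Adjusted over the list alone 1 member passed, and 0 over all genes. Guides of Calr, the chaperone calreticulin, had a log2 of 3.79 ± 0.33 over 3 guides, and Ost4, Alg11 and Uggt1 had 1.80 ± 1.55, 1.46 ± 3.59 and 1.25 ± 0.19. The list lost its call with non-targeting scaling (0.288), and 1 list, peroxisome biogenesis, was left without Siglec-F high replicate 1, high replicate 2 or low replicate 2. Of the Mediator list of 12 genes, a transcription coactivator complex, fry gave a lower direction (FDR 0.0157) while camera did not pass (adjusted p = 0.874); its mean was -0.09 and its median 0.26. Mean and median are centred on the median guide, at -0.22 in this comparison, while fry used uncentred values.

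The gene lists of the cytokines in the medium did not pass, which does not decide on the pathways themselves. Camera looks for a shift of a list in 1 direction, so members with opposite effects would cancel. Of 17 GM-CSF signalling genes, 5 had enough guides to be tested (adjusted p = 0.874, median log2 0.19; 0.486 for all 17 with no filter), among them Socs1 at 1.48 ± 0.52, Pim1 at 0.11 ± 2.22 and Cish at -0.20 ± 1.497. Guides of Csf2ra, Csf2rb and Jak2, chosen after their values were seen, were near the floor of reads in high and low libraries. Their mean log2 against non-targeting guides was -5.56, -5.36 and -6.13. An effect of their loss on Siglec-F could not be seen, with or without the filter. The 17 TGF-beta signalling genes had a median of -0.44 (0.967), with Bmpr2 at -2.30 ± 0.91, Furin at -1.03 ± 2.73 and Ski at -0.31 ± 2.48. The 20 alveolar macrophage transcription factors had a median of -0.71 (0.780), with Bach2 at -2.29 ± 1.30, Gata6 at -1.65 ± 1.60 and Egr1 at -0.86 ± 0.55. Adjusted over the list alone, 0 genes passed in each of these 3 lists by limma and alpha-RRA; at an unadjusted p under 0.05 there were 0 higher and 0 lower in GM-CSF signalling, 2 and 0 in TGF-beta signalling and 1 and 1 among the transcription factors. Olfactory receptors (1003 genes, median -0.13, adjusted p = 0.844) and keratin and crystallin genes (103 genes, -0.06, 0.679), the negative controls, did not pass.

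Siglec-F low was next compared with unsorted input. Siglecf guides rose 22.6-fold (log2 4.50 ± 0.87 over 4 guides, adjusted p = 0.0206), as did those of Usp9x, a deubiquitinase (28.0-fold, 4.81 ± 0.52, 0.0247), and of Etnk1, an ethanolamine kinase (10.8-fold, 3.43 ± 0.15, 0.0206). Guides of Nedd8, the modifier that activates cullin ligases, fell by 2.85 on the log2 scale (SD 0.09, 3 guides), those of Gm11758 by 2.77 (SD 0.22) and those of Atp6v1b2, a subunit of the proton pump of lysosomes, by 2.66 (SD 0.16), each with an adjusted p of 0.0392. limma with alpha-RRA called 3 genes higher and 4 lower, these among them, with 916 and 963 at an unadjusted p under 0.05. The next by score were Pex6 (3.67 ± 0.89) and Poll, a DNA polymerase (1.43 ± 4.22), both with 0.162, and Dph5, of diphthamide synthesis (-2.85 ± 0.16, 0.0511).

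All of these calls depended on the fit. edgeR and limma on the compared groups alone called 0 and 0, edgeR with 929 and 958 at an unadjusted p under 0.05 and limma with 917 and 949. Scaling on non-targeting guides gave 0 higher and 7 lower, and equal totals 4 and 0. The folds moved with the inputs too: without Input replicate 2 and without Input replicate 1, Siglecf had a log2 of 3.15 ± 0.45 and 5.80 ± 1.30, Usp9x 3.16 ± 0.55 and 6.41 ± 0.59, and Etnk1 2.88 ± 0.39 and 3.94 ± 0.22. Over all settings Nedd8 ran from -4.63 to -1.77, the latter with pseudocount 20, Gm11758 from -4.84 to -1.63 and Atp6v1b2 from -4.38 to -1.67. Without Input replicate 2 and without low replicate 2, Nedd8 had -3.18 ± 0.57 and -3.51 ± 0.38, and Atp6v1b2 -2.06 ± 0.28 and -3.43 ± 0.26. The small SDs between guides in the main fit therefore do not fix the size of these falls. Siglecf lost its call without Siglec-F high replicate 1 (0.563), high replicate 2 (0.61) or low replicate 2 (0.0852). When each library was left out in turn, Nedd8 lost its call in all 6 fits (0.0598 to 0.242). Etnk1 lost it in all but the fit without high replicate 1 (0.0808 to 0.363), Usp9x in all but the fit without Input replicate 1 (0.0522 to 0.659) and Gm11758 in all but the fit without high replicate 2 (0.0962 to 0.338). Atp6v1b2 lost it without high replicate 1, high replicate 2, low replicate 1 or Input replicate 2 (0.0866 to 0.21). Dph5 passed without low replicate 1 (0.0454). The count higher was 0 without high replicate 2, 1 without either low replicate and 6 without Input replicate 1; the count lower was 1 without high replicate 1, 2 without high replicate 2 or low replicate 1 and 0 without Input replicate 2.

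By camera, 6 lists passed in the low libraries against input, and 0 with an estimated correlation. Peroxisome biogenesis was higher (12 genes, median log2 1.80, mean 1.71, adjusted p = 0.000283, 0.799 with an estimated correlation, 5 members adjusted over the list alone), with Pex6 at 3.67 ± 0.89, Pex10 at 3.10 ± 1.94 and Pex16 at 2.93 ± 1.66. The growth restraint list was higher too (20 genes, 1.97 and 2.09, adjusted p = 0.00164, 0.870 with an estimated correlation, 6 members over the list alone). Its examples were Rb1, the retinoblastoma protein (4.23 ± 1.36), Lztr1 (3.50 ± 1.11) and Rasa2 (2.77 ± 1.23), which curb Ras signalling, and the cell cycle inhibitor Cdkn1a (2.998 ± 1.38). Over all genes 0 members of these 2 lists passed by limma and alpha-RRA, with 6 and 7 higher at an unadjusted p under 0.05.

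Mediator genes were lower against input in the low libraries (12 genes, median -1.25, adjusted p = 0.000679, 0.675 with an estimated correlation, fry 0.00046), among them Med17 at -2.58 ± 0.48, Med10 at -2.47 ± 0.48, Med7 at -1.85 ± 0.80 and Med1 at -1.15 ± 1.30. Lower as well were the V-ATPase (15 genes, -0.88, adjusted p = 0.0123, 0.870 with an estimated correlation), N-glycan assembly (20 genes, -0.95, adjusted p = 0.0237, 0.799 with an estimated correlation) and the SWI/SNF chromatin remodelling genes (18 genes, -0.62, adjusted p = 0.0441, 0.870 with an estimated correlation), for which fry, on values not centred on the median guide, gave the opposite sign. Among their members were Atp6v0e at -2.02 ± 0.51, Tmem199 at -1.53 ± 1.48 and Atp6v0d2 at -1.03 ± 1.93; Pmm2 at -2.65 ± 0.33, Alg10b at -1.87 ± 0.70, Canx at -0.84 ± 1.73 and Ost4 at -0.32 ± 2.47; and Smarca4 at -2.38 ± 0.85, Dpf2 at -2.28 ± 0.13, Smarcd2 at -1.49 ± 1.69 and Smarcc2 at -0.80 ± 2.07. Adjusted over the list alone, 2 genes of Mediator, 1 of the V-ATPase, 1 of N-glycan assembly and 2 of SWI/SNF passed. Over all genes Atp6v1b2 passed. Without low replicate 2, 2 of the 6 lists were left: V-ATPase had 0.265, SWI/SNF 0.306, N-glycan assembly 0.137 and growth restraint 0.0666. SWI/SNF and growth restraint were also lost without high replicate 1 (both 0.0517) or high replicate 2 (0.0735 and 0.0675), and N-glycan assembly without low replicate 1 (0.0941) or Input replicate 2 (0.116).

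Siglec-F high was compared with the same input libraries, so its values are not independent of those of the low fraction. Among genes with the smallest scores, guides of Bcl7b, of the SWI/SNF family of remodellers, had a log2 of 3.57 ± 1.06 over 4 guides, Chd2, another remodeller, 2.81 ± 0.57, Epcam, an adhesion molecule, 2.49 ± 0.25, Olfr1048 2.05 ± 2.13 and Rnf112 1.33 ± 3.06. In the other direction were Snrnp40, of the spliceosome (-3.29 ± 0.12), Dph5 (-3.26 ± 0.15), Atp6v1b2 (-3.23 ± 0.39), Cdca8, needed for chromosome segregation (-3.09 ± 0.51), and Wdr36, of ribosome assembly (-2.90 ± 0.26). Adjusted p was 0.28 to 0.574 for the first 5 and 0.0923 for the others. limma with alpha-RRA called 0 genes higher and 0 lower, with 877 and 1017 at an unadjusted p under 0.05; edgeR called 0 and 0 as well, with 849 and 1046 at that unadjusted threshold. Without Input replicate 1 limma called 3 higher and 14 lower, among the latter Atp6v1b2 (0.0165), Snrnp40 (0.0206), Wdr36 (0.0371) and Dph5 (0.0448). Non-targeting scaling gave 0 and 5, and equal totals 3 and 0.

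By camera 11 lists passed in the high libraries against input, 10 of them lower, and 0 with an estimated correlation (adjusted p of 0.395 to 0.927). N-glycan assembly had the lowest median of the lists past the test (20 of 41 genes after the filter, median -1.96, 1 above 0, adjusted p = 1.02e-07, 0.395 with an estimated correlation) and held without each library in turn; its examples were Uggt1 at -2.52 ± 0.57, Pmm2 at -2.33 ± 1.14, Ost4 at -2.25 ± 0.93 and Canx at -2.10 ± 0.97. Genes of ER targeting and signal peptide processing had a median of -1.94 (13 genes, 0.0176, 0.443 with an estimated correlation, fry higher with 0.984), with Srp72 at -2.93 ± 0.63, Pdia6 at -2.92 ± 0.24, Ssr1 at -2.34 ± 0.58 and Pdia4 at -2.10 ± 0.60. Mediator had -1.66 (12 genes, 0.00946, 0.443 with an estimated correlation), with Med17 at -2.88 ± 0.32, Med10 at -1.85 ± 1.99, Med29 at -1.65 ± 0.89 and Med25, in the opposite direction, at 0.93 ± 2.73. COMPASS and MLL histone methylation genes had -1.52 (12 genes, 0.03, 0.443 with an estimated correlation), with Kmt2c at -2.00 ± 0.86, Setd1a at -1.93 ± 2.61, Mllt1 at -1.17 ± 2.10 and Paxip1 at 0.46 ± 2.98.

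Lists of membrane traffic, nutrient sensing and respiration were lower too in the high libraries by camera with the preset correlation. With an estimated correlation the calls were lost (0.443 for complex I and 0.648 for the other 3), and for the clathrin, mTORC1 and Golgi traffic lists fry gave the higher direction, without passing (0.984). Its values were not centred on the median guide, which lay at 0.99 in this comparison. It gave the higher direction for the negative controls too, so its direction here does not conflict with camera. Clathrin, AP-2 and endosomal sorting had a median of -1.40 (23 genes, 0.0112), with Commd1 at -1.72 ± 1.81, Ap2a2 at -1.68 ± 2.18, Vps16 at -1.36 ± 2.50 and Cltc, the clathrin heavy chain, at -0.95 ± 3.01. The mTORC1 and GATOR list, of nutrient sensing at the lysosome, had -1.37 (21 genes, 0.0112), with Flcn at -2.49 ± 1.40, Rragc at -1.90 ± 2.04, Lamtor2 at -1.67 ± 2.14 and Depdc5 at -1.13 ± 2.25. Respiratory complex I had -1.28 (15 genes, 0.0112), with Ndufb7 at -2.40 ± 0.22, Ndufb10 at -2.37 ± 0.14, Ndufs3 at -2.20 ± 1.08 and Ndufs8 at -0.62 ± 2.59. COG, GARP, retromer and TRAPP, of Golgi traffic, had -1.21 (20 genes, 0.0112), with Trappc5 at -3.32 ± 0.44, Trappc2l at -2.84 ± 0.36, Trappc4 at -2.55 ± 0.57 and Trappc13 at -1.78 ± 2.95.

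SWI/SNF genes had a median of -1.04 in the high libraries (18 genes, 0.0112, 0.648 with an estimated correlation), with Dpf2 at -2.61 ± 0.85, Smarcd2 at -1.84 ± 2.12, Brd7 at -1.70 ± 1.39 and Smarca4 at -1.27 ± 2.53. The V-ATPase had -1.03 (15 genes, 0.03, 0.746 with an estimated correlation), with Atp6ap1 at -2.56 ± 0.28, Tmem199 at -2.27 ± 0.92 and Ccdc115 at -2.12 ± 1.34. For both lists fry, on values not centred on the median guide, gave the higher direction, without passing (0.984). The growth restraint list was higher (20 genes, 1.65, 0.0438, 0.927 with an estimated correlation), with Chek2 at 2.80 ± 0.75, Taok1 at 2.08 ± 1.29, Cdkn2a at 2.03 ± 1.22 and Bax at 0.24 ± 2.52. Adjusted over the list alone, the members lower were 4 in the Golgi traffic list, 3 in ER targeting, 2 each in complex I and the V-ATPase, 1 each in Mediator, COMPASS and SWI/SNF, and 0 in N-glycan assembly, the clathrin list and the mTORC1 list, where limma and alpha-RRA gave 4, 6 and 5 at an unadjusted p under 0.05. In growth restraint and SWI/SNF, 1 member each was higher over the list alone. Over all genes 0 members passed.

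Without Siglec-F high replicate 2, 2 of these 11 lists were left, N-glycan assembly and Mediator; V-ATPase and growth restraint then had an adjusted p of 0.605, ER targeting and SWI/SNF 0.204 and the others 0.144. Without high replicate 1, Mediator (0.106), COMPASS (0.0885) and growth restraint (0.196) were lost; without Input replicate 1, the mTORC1 list (0.0522) and COMPASS (0.0638). V-ATPase (0.0577) and growth restraint (0.135) were lost without Input replicate 2, and growth restraint without low replicate 2 (0.0678). The median guide itself lay at 0.99 in this comparison as deposited, -0.67 with non-targeting scaling and 0.37 with equal totals, and in the low libraries against input at 0.64, -0.42 and -0.42.

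Among filtered guides the cytokine and transcription factor lists did not pass against input either, but 5 of 17 GM-CSF signalling genes kept enough guides for that test. With no filter, all 17 GM-CSF signalling genes were lower as a list and passed by camera, in the low (adjusted p = 0.00112) and the high libraries (0.000229), but not with an estimated correlation (0.468 and 0.559). With no filter and the preset correlation 19 and 18 of 29 lists passed, in the high libraries with the olfactory receptor control among them (0.0407). TGF-beta signalling (22 genes, 0.251 and 0.342) and the transcription factors (26 genes, 0.312 and 0.367) did not pass with no filter. Among filtered guides the adjusted p in the low libraries was 0.913 for GM-CSF signalling (Socs1 1.10 ± 2.43, Socs3 0.99 ± 1.98, Cish 0.29 ± 0.90), 0.929 for TGF-beta signalling (Smurf1 -1.20 ± 2.28, Smad3 -1.01 ± 1.37, Furin -0.32 ± 2.64) and 0.385 for the transcription factors (Pparg -2.07 ± 0.88, Bach2 -2.04 ± 0.24, Mitf -1.34 ± 1.78). In the high libraries it was 0.967 for GM-CSF signalling (Pim1 -0.83 ± 1.495, Socs1 -0.51 ± 2.04, Socs3 0.72 ± 1.98), whose test and mean (-0.10) were lower while its median was 0.88. TGF-beta signalling had 0.967 (Tgif1 -2.59 ± 0.37, Smad3 -1.27 ± 1.34, Tgif2 -0.87 ± 1.78). The transcription factors had 0.881 (Runx1 -2.64 ± 1.02, Pparg -2.36 ± 1.002, Tcf7l2 -0.66 ± 2.25), with a lower test and median (-0.22) and a mean of 0.002.

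The authors' deposited table of the same low and high libraries was compared with the fit made here, and gave a Spearman's rho of 0.905 across genes and 0.956 across guides, which are not independent replicates. In the authors' deposited table, ranked by the median guide, the first 10 genes higher in the low fraction were Pptc7, Cic, Rwdd1, Ptrh2, Siglecf, Ptn, Chgb, Il1f8, Khnyn and Tnrc6c, and the first 10 lower were Lcmt1, Dclk2, Styx, Prr5, Wbp2, Cplx3, Olfr395, Kdm7a, Spg21 and Lama3. Siglecf was the fifth in the authors' deposited table, with a median log2 of 4.91. In the fit made here Cic, a transcriptional repressor, had a log2 of 5.34 ± 0.64 over 4 guides (40.5-fold). Its adjusted p by limma and alpha-RRA was 0.685, and 0.00412 on the sorted libraries alone. Cic did not pass without any 1 of the sorted libraries. Ptrh2, a mitochondrial peptidyl-tRNA hydrolase, had 3.45 ± 1.68 (0.293), Il1f8, an interleukin-1 family cytokine, 3.85 ± 0.98 (0.464), Cplx3, a synaptic protein, -3.32 ± 0.56 (0.755), and Styx, a phosphatase-like protein, -3.20 ± 1.02 (0.792). Guides of Kdm7a, a histone demethylase, ran from -4.08 to 3.85, and those of Pptc7 from -4.58 to 4.06.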

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

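All tests of explanations in this part were chosen after the result was seen, except the rank correlation of low reads with Input replicate 2. The added bound named in the last paragraph also came after its value.

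A non-targeting guide, which cuts no gene and enters no comparison, took 3.46% of the reads of Input replicate 1 (1393494 reads), against a median of 14 reads per non-targeting guide in that library. It took 0.142% to 0.203% of the other 5 libraries. No group had the 4 libraries that a test for a stray library needs.

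The most abundant guides of the other 5 libraries recurred in Input replicate 2, whose reads were otherwise even. At the 54 targeting guides with over 100000 reads summed over the other 5 libraries, Input replicate 2 had a median of 2700 reads, against 395 over all targeting guides. Its reads were a near constant share of that sum, with a median of 1.20% and an SD of 0.466 on the log2 scale, which is what reads carried over or misassigned between libraries would give. Had the same expanded cells been present at their share of the other libraries, the share would be near the ratio of depths, 24.0%, so this biological explanation is argued against. A small admixture of the expanded cells, at the step of cells or of DNA, may give the same share and was not tested. Recurrence was not particular to Input replicate 2. The Cnot6l guide took 35.4% of Input replicate 1, 1.10% to 1.54% of the sorted libraries and 1.12% of Input replicate 2. A Snx3 guide took 34.9%, 1.05% to 1.45% and 1.07%. Whether the sorted libraries, used in every comparison, hold reads of this kind was not tested.

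Input replicate 2 spread its reads evenly while many guides of the sorted libraries sat at 1 to 15 reads. Among the 16381 guides with 15 or fewer reads in all 4 sorted libraries, the sum of those reads followed Input replicate 2 across guides with a Spearman's rho of 0.665. This is consistent with reads carried over from that library, but guides common in the starting pool could give the same, so both stay open. That the library held guides never selected by growth of knockout cells is argued against: the median ribosomal guide was at log2 -0.88, below the lowest of 10000 random gene sets, -0.30. The bound first written, below -1, was not met, and the bound of random sets was added after the value was seen.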

How the results depend on the processing

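edgeR on the sorted libraries, the sorted libraries with a mean of at least 50 reads, lists on the sorted libraries, and lists with no filter and an estimated correlation were chosen after seeing the data; the other settings were planned. For genes higher and lower in Siglec-F low than high, main counts 0 and 0 became 5 and 1 at a threshold of 0.25, 1 and 1 with pseudocount 20, 0 and 1 with no filter, 1 and 1 with a mean of at least 50, 4 and 1 with non-targeting scaling, 7 and 1 with equal totals, 4 and 1 with edgeR, 4 and 1 with a replicate block, 4 and 0 with the groups compared alone, 10 and 1 with edgeR on the sorted libraries, and 5 and 1 with the sorted libraries at a mean of at least 50 reads; leaving out each library gave 0 to 2 higher and 0 to 0 lower. For low against input, 3 and 4 became 3 and 11 at a threshold of 0.1, 5 and 70 at 0.25, 3 and 2 with pseudocount 1, 3 and 7 with pseudocount 20, 1 and 0 with no filter or a mean of at least 50, 0 and 7 with non-targeting scaling, 4 and 0 with equal totals, 0 and 0 with gene medians, edgeR or the groups compared alone, and 2 and 1 with a block; leaving out each library gave 0 to 6 and 0 to 3. For high against input, 0 and 0 became 0 and 21 at a threshold of 0.1, 0 and 60 at 0.25, 0 and 2 with pseudocount 20, 1 and 0 with no filter, 0 and 5 with non-targeting scaling and 3 and 0 with equal totals; leaving out each library gave 0 to 3 and 0 to 14, both highest without Input replicate 1. Lists past the test were 2, 6 and 11 in these comparisons, 0 in each with an estimated correlation, with or without the filter, and 1, 19 and 18 with no filter; the 18 include a negative control, olfactory receptors, higher in high than input (1078 genes, adjusted p = 0.0407). For low against high, 1 list passed with gene means, a block or non-targeting scaling. Leaving out each library gave 1 to 3, 2 to 6 and 2 to 11. The cause was not tested.

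Of the genes named between low and high that passed no test, 4 changed sign in some setting: Pim1 was at -0.055 with pseudocount 1 and -0.10 without high replicate 2, Cish at 0.57 without high replicate 1 and 0.46 without low replicate 1, Furin at 0.062 without high replicate 1, and Ski at 0.50 without high replicate 2 and 0.13 without low replicate 2. Leaving out each library, Pim1 ran from -0.10 to 0.19, Cish from -1.21 to 0.57, Furin from -2.35 to 0.062 and Ski from -1.35 to 0.50. The cause was not tested. Over the alternatives for genes named between low and high, 732 of 777 values kept their direction and side of the threshold, and 38 newly passed it. For low against input 86 of 165 kept both, 76 lost the threshold and 3 newly passed it; for high against input 157 of 165 kept both and 8 newly passed. Of list results, 19 of 30, 58 of 84 and 106 of 154 kept both, and 11, 26 and 48 lost the threshold. The share of guides under 10% of the median non-targeting reads in Input replicates 1 and 2 was 36.9% and 0.610% for ribosome genes, 21.8% and 0.641% for proteasome genes and 4.17% and 1.04% for growth restraint. That median was 14 and 438 reads, so the bound lay near the floor in Input replicate 1. Equal replicate numbers showed no pairing: deviations of same-numbered libraries correlated across guides at 0.03, 0.22 and 0.08. Guides at 1 to 15 reads, up to 66.5% of a library, limit what can be seen of genes whose loss is lethal.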

Other observations

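The tests of random lists without the top guide, of abundance-matched lists and of heme synthesis genes were chosen after the result was seen, as were the genes named in the next 2 paragraphs.

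Guides against some receptors of the cytokines in the medium were near the floor of reads in the sorted libraries. Relative to the median non-targeting guide, guides of Csf2ra and Csf2rb, the chains of the GM-CSF receptor, were at a mean log2 of -5.56 ± 1.22 and -5.36 ± 1.02 (SD, 4 sorted libraries), and those of Jak2, the kinase bound to it, at -6.13 ± 1.10. Of 19670 genes, 1.67%, 3.09% and 0.107% lay lower. Stat5b was at -5.10 ± 0.75. Guides of Tgfbr1 and Tgfbr2, the TGF-beta receptors, were at -5.23 ± 0.80 and -5.46 ± 0.37, and those of Smad4 at -5.23 ± 0.77. Some other receptor genes on the GM-CSF and TGF-beta signalling lists were not at the floor. Csf2rb2, listed with GM-CSF signalling but not 1 of the chains named above, was at -3.45 ± 0.88, with 20.5% of genes lower. Tgfbr3, a TGF-beta co-receptor, was at -0.65 ± 0.27. The macrophage regulators Spi1, Cebpb and Rxra were at -5.02 ± 1.67, -5.68 ± 0.79 and -5.26 ± 0.94, while Klf2, Egr2 and Nfe2l2 of the same transcription factor list were at 1.56 ± 0.37, 1.76 ± 0.48 and 2.03 ± 0.11. The median guide of that list of 26 genes was at -4.33 and -1.19 in the high and -2.85 and -2.08 in the low libraries, and that of 22 TGF-beta signalling genes at -4.51, -1.15, -2.71 and -2.56. The median guide of all 17 GM-CSF signalling genes was at -5.50 and -5.51 in the high and -4.10 and -4.20 in the low libraries, against -1.58 and -0.38 in the inputs and -3.25, -0.58, -1.29 and -0.61 for olfactory receptors in the sorted libraries. The median non-targeting guide had 180 and 181 reads in the high, 67.5 and 72.5 in the low and 14 and 438 in the input libraries. A guide at the floor lies lower where that median is higher, so differences between libraries in such values do not measure loss. Irf8, a macrophage regulator, was at 3.92 ± 0.82, above 99.9% of genes.

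Single guides held large shares of reads. A guide of Prkag2, a subunit of an energy-sensing kinase, made up 1.90% and 1.77% of the high libraries, 8.01% and 7.07% of the low libraries and 0.1103% and 0.123% of the inputs. A guide of Nf1, which curbs Ras signalling, made up 0.290% and 0.289% of the high and 3.40% and 3.07% of the low libraries. An Itgam guide made up 1.68% and 7.87% of the high and 0.208% and 3.60% of the low libraries. In the sorted libraries the other 3 guides of each gene together held up to 0.000142% for Prkag2, 0.0564% for Nf1 and 0.0197% for Itgam, so these shares belong to 1 guide each.

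Guides of peroxisome biogenesis genes were higher in Siglec-F low. The list median stayed above 100% of 10000 random lists when each gene's top guide was left out (1.93, against a 95th percentile of 0.04), which argues against a single expanded guide per gene. It also lay above 100% of random lists matched on mean abundance, which argues against depth. There the list median was 2.67, from the median guide fold of each gene, and the highest random list had 1.59; the 3.04 given for the camera test comes from guide medians taken in each library first. In the high libraries the list was below olfactory receptor genes by a mean log2 of -0.71 (-0.61 and -0.80), well inside the spread of its guides (quartiles -5.18 and 0.19 in high replicate 1). In the inputs the list was at -0.21 and -0.07, and olfactory receptors at -0.32 and -0.10. These values do not decide on a growth advantage of these cells, which stays open. Loss of peroxisomes may lower surface Siglec-F, but this hypothesis was found on the same data and tested on no other, and camera with an estimated correlation gave an adjusted p of 0.928.

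Cutting near Siglecf might remove Siglecf itself, so genes within 1 Mb of it outside the Siglec family were tested. The 37 genes had a median log2 of 0.22 between low and high (one-sided permutation p = 0.166), which gives no support to that explanation. Heme synthesis genes might also be enriched in sorted cells: the median guide of 10 genes was above non-targeting guides in all 4 sorted libraries (0.53 to 1.09). It was at 1.09 in unsorted Input replicate 1 and at 0.08 in Input replicate 2, so the inputs disagree. In the sorted libraries Alas1 (4.14 ± 0.35) and Fech (3.34 ± 0.26) were high, but only 4 of the 10 genes had a mean above 0, and Uros (-5.07 ± 1.64) and Urod (-4.28 ± 0.38) lay far below, so the list as a whole decides nothing.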
